A study of Mus musculus with 12 samples.

How the data were processed

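The study measured gene expression by RNA sequencing in 12 libraries of MC38 cells, 3 for each combination of guide (sgControl or sgHcar1) and treatment (PBS or 20 mM lactate for 24 hours). Per the labels, total RNA was extracted with Trizol and 1 µg went into a TruSeq RNA library. The authors deposited 1 table of FPKM, that is fragments normalised for the length of the gene model and for the fragments of the library, with 1 value per gene and library. Its headers name the unit. The authors' notes name HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mouse build GRCm38, but they do not say which fragments make up the library total or which filters were applied. The gene identifiers in the table are those of the Ensembl annotation of the C57BL/6NJ strain, with 1233 further entries for unannotated genes, and 11920 of the 42329 entries have no symbol. All 12 value columns were used. Columns were assigned to groups from their letters, which follow the order of the labels, with the letters of the sgHcar1 columns read by elimination.

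The table holds no counts and no gene lengths, so read depth is unknown and a test on counts was not run. Relative depth was estimated from genes whose highest FPKM was at most 0.5, where the ratio of values between libraries takes steps set by whole fragments, and it was 0.746 to 1 of the deepest library.

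FPKM values were taken as deposited and tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Genes with at least 1 FPKM in at least 3 libraries were kept, which left 13736 genes, of which 1922 had no symbol. A linear model with 1 mean per group was fitted to all 12 libraries, without a replicate block, and moderated with an intensity trend. Tests were two-sided, and Benjamini-Hochberg adjustment was made over all genes within each of 5 contrasts, with a threshold of 0.05. The contrasts were lactate against PBS within sgControl and within sgHcar1, the difference between these lactate effects, and sgHcar1 minus sgControl in PBS and in lactate. Genes below the filter that were to be named in any case were tested with an exact permutation test of 6 against 6 libraries.

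Gene lists were fixed before the data were examined: 30 lists with 711 symbols, of which 656 had an entry. The 26 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over lists within a contrast. Member counts are given over all genes tested and adjusted over the list alone. Lists with fewer than 5 tested members have levels only.

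Named genes followed a rule also set in advance. Hcar1, Hcar2, Ccl2 and Ccl7 were always named. For each contrast the rule took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 FPKM and a standard symbol, and for contrasts of 2 groups with no overlap between the groups' libraries. It also took up to 4 members of each list described, by size of change among those past the threshold. Genes given only as levels or to name a list's content, such as cell type markers, were chosen after their values were seen. Some genes that the rule took are not reported here.

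Agreement between lactate effects was measured by correlation across genes and by Fisher's exact test on the overlap of called genes. Principal components used 8262 genes. The model was tested on simulated data: of 50 genes per fold set to change in simulated libraries, 30% to 68% were recovered at 1.25-fold, 72% to 82% at 1.5-fold, 88% to 96% at 2-fold and 90% to 100% at 4-fold, and 1.24% to 5.56% of the calls were unchanged genes. Only these genes of 13736 were changed, while 59.1% to 82.2% of genes were called in the data, so the percentages hold for the simulated setting alone.

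Alternatives set in advance were a pseudocount of 0.1, no filter on low values, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, no variance trend, a replicate block, array weights, a fold of at least 2, a fit with only the compared groups, and leaving out each replicate in turn. Rescaling each library to a sum of 1000000 was added after seeing the data. Order and chromosome of genes came from the RefSeq annotation of GRCm38, matched by symbol. Figures and summary tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.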

Results

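RNA was sequenced from MC38 cells, a mouse colon adenocarcinoma line, that carried either a control guide RNA (sgControl) or a guide against Hcar1 (sgHcar1), the gene of a G protein-coupled receptor for lactate. Each of the 2 populations was kept in medium with saline vehicle (PBS) or with 20 mM lactate for 24 hours, which gave 4 groups of 3 libraries and 12 libraries in all. The values are FPKM for 42329 entries, of which 1233 are for unannotated genes. The files give no read counts, so the depth of each library in reads is unknown. From the smallest steps between low FPKM values, the depth of each library relative to the deepest one was 0.746 to 1. Group means were 0.955 for sgControl in PBS, 0.943 for sgControl in lactate, 0.891 for sgHcar1 in PBS and 0.775 for sgHcar1 in lactate. Between 11758 and 12128 genes per library reached 1 FPKM. The FPKM of a library added up to 310109 to 324562.3 in sgControl cells, 362814.6 to 367976.7 in sgHcar1 cells in PBS and 411996.2 to 421984.3 in sgHcar1 cells in lactate. Levels below are mean FPKM ± SD over 3 libraries, and changes are log2 differences of FPKM + 1 ± standard error, from limma with 3 libraries per group. This scale understates changes of genes at low levels. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries alone.

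The targeted gene itself could not be followed. Hcar1 was listed at 0 in all 6 sgControl libraries and in 5 of the 6 sgHcar1 libraries, with 0.0196 FPKM in the remaining one (exact two-sided permutation test on 6 libraries per guide, p = 1, where the smallest possible p is 0.00216). Hcar2, a related receptor for hydroxybutyrate and niacin, reached at most 0.0323 FPKM, in sgControl cells, and was listed at 0 in all 6 sgHcar1 libraries (exact permutation p = 0.182). Whether Hcar1 message was lost could therefore not be seen from these values.

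The libraries fell into their 4 groups. Correlation of log2 levels between libraries was 0.990 to 0.992 within a group, 0.918 to 0.947 between treatments within a guide and 0.806 to 0.837 between guides within a treatment. The first principal component separated the guides and held 70.2% of the variance over 8262 genes, and the next one separated lactate from PBS and held 23.9%. Markers of leukocytes and endothelium were low. Ptprc, the pan-leukocyte antigen, reached at most 0.0063 FPKM in every library, the most abundant leukocyte marker was Cd14 at 4.29 to 13.9 FPKM in the group means, and the most abundant endothelial marker, Flt1, peaked at 1.88 FPKM. Fibroblast markers were mixed. In PBS, Fbln2 was at 136 and 44.7 FPKM in sgControl and sgHcar1 cells, Col3a1 at 67.2 and 1.56 FPKM, and Col1a2 at 45.5 and 114.6 FPKM, while Lum and Thy1 were listed at 0.

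The first comparison asked what 20 mM lactate did to sgControl cells. Genes of the amino acid and integrated stress response were among the largest rises. Trib3, a pseudokinase induced by ATF4, rose from 8.39 ± 1.38 to 226 ± 4.19 FPKM (log2 change 4.61 ± 0.08, n = 3 per group), and Chac1, which degrades glutathione, rose from 11 ± 0.309 to 224 ± 13.6 FPKM (4.23 ± 0.06). Hmox1, which breaks down heme, rose from 8.65 ± 0.926 to 239 ± 11.3 FPKM (4.64 ± 0.08). In the other direction, Ldha, the enzyme that makes lactate from pyruvate, fell from 1096 ± 41.9 to 201 ± 8.78 FPKM (-2.44 ± 0.04), and Egln3, a hypoxia-induced oxygen sensor, fell from 18.9 ± 1.28 to 1.43 ± 0.154 FPKM (-3.03 ± 0.07).

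Of 13736 genes tested, 9031 passed an adjusted p of 0.05 in limma, 4650 higher and 4381 lower in lactate. At least 2-fold changes were seen for 990 of them (585 higher, 405 lower). The 10 largest rises also held Gdf15, a stress cytokine (4.44 ± 0.11), Gadd45a (4.42 ± 0.05), the transcription factors Atf3 (4.24 ± 0.09) and Ddit3 (3.92 ± 0.06). Among them too were Car6, a carbonic anhydrase (4.10 ± 0.06), Sh2d6 (3.91 ± 0.07) and Ppp1r15a, which guides the phosphatase that reverses eIF2 phosphorylation (3.68 ± 0.04). The 10 largest falls also held the helix-loop-helix inhibitors Id3 (-2.88 ± 0.10) and Id2 (-2.78 ± 0.13) and the peptide hormone gene Apln (-2.70 ± 0.06). The rest were the hypoxia-induced genes Nrn1 (-2.72 ± 0.05), Ankrd37 (-2.65 ± 0.13) and Bnip3 (-2.56 ± 0.16), the microRNA locus Mir210 (-2.45 ± 0.31) and the protease gene Klk10 (-2.60 ± 0.09). The largest adjusted p among the 10 rises was 8.21e-11 and among the 10 falls 3.79e-05.

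Ccl2 and Ccl7, which encode chemokines that attract monocytes, were among the abundant transcripts of sgControl cells. Ccl2 rose with lactate from 597.5 ± 29.7 to 921 ± 58.5 FPKM (0.62 ± 0.07, limma adjusted p = 9.86e-06), and Ccl7 rose from 181 ± 3.42 to 260 ± 22.96 FPKM (0.52 ± 0.06, adjusted p = 2.39e-05). With a pseudocount of 0.1 the changes stayed at 0.62 and 0.52 but the calls ended, with adjusted p of 0.124 for Ccl2 (range over the alternatives 3.57e-06 to 0.124) and 0.123 for Ccl7 (1.05e-05 to 0.123). The sgControl libraries did not overlap between lactate and PBS (Ccl2 853 to 958 against 563 to 616 FPKM, Ccl7 237 to 283 against 178 to 185 FPKM). The fit shares its spread over all 12 libraries, so the lost calls also depend on the sgHcar1 libraries, where both genes were near 0.

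Gene lists fixed in advance moved together in these cells. All 37 tested ATF4 targets rose (median log2 change 2.01, camera adjusted p = 5.68e-22), among them Trib3, Gdf15, Atf3 and Chac1. In the unfolded protein response, 22 of 23 genes rose and 1 fell (median 1.36, adjusted p = 1.11e-12), with the chaperone Hspa5 at 3.27 ± 0.02, the transcription factor Xbp1 at 2.87 ± 0.05 and Herpud1 at 2.79 ± 0.03. Of 28 NF-kB targets 23 rose, 2 fell and 3 did not pass (median 0.80, adjusted p = 1.54e-07), led by the prostaglandin synthase gene Ptgs2 (3.48 ± 0.05), Lcn2 (2.53 ± 0.12) and Saa3 (2.43 ± 0.12). Of 24 lysosome and autophagy genes 20 rose, 1 fell and 3 did not pass (median 0.39, adjusted p = 1.95e-05), with the autophagy receptor Sqstm1 at 2.73 ± 0.03.

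Cell division genes fell as a body in the same cells. All 30 mitosis genes fell (median -1.29, camera adjusted p = 1.10e-17), including the kinase Plk1 (-2.02 ± 0.07) and the cyclins Ccnf (-2.08 ± 0.07) and Ccna2 (-1.75 ± 0.04). All 30 DNA replication genes fell too (median -0.76, adjusted p = 1.11e-12), with the cyclins Ccne1 at -1.83 ± 0.07 and Ccne2 at -1.49 ± 0.08. In the nuclear-encoded respiratory chain 31 of 32 genes fell and 1 rose (median -0.59, adjusted p = 2.94e-10), among them Ndufb3 (-1.19 ± 0.05) and Ndufa4 (-1.11 ± 0.05).

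Metabolic and antiviral lists moved with less certainty. Of 21 hypoxia-inducible genes outside glycolysis 18 fell, 1 rose and 2 did not pass (median -0.92, camera adjusted p = 1.79e-07, but adjusted p = 0.0961 with an estimated correlation). Of 14 glycolysis genes 10 fell and 3 rose (median -0.69, adjusted p = 0.000865, and adjusted p = 0.14 with an estimated correlation), with Pfkl at -2.02 ± 0.04 and Tpi1 at -1.90 ± 0.04. In lactate and pyruvate handling 8 of 16 fell and 4 rose (median -0.15, adjusted p = 0.0302, and adjusted p = 0.164 with an estimated correlation). The lactate exporter gene Slc16a3 (-2.39 ± 0.04) and Pdk1, a brake on pyruvate oxidation (-2.08 ± 0.05), were among those that fell. Of 24 cholesterol genes 19 fell, 1 rose and 4 did not pass (median -0.53, adjusted p = 2.10e-06, and adjusted p = 0.107 with an estimated correlation), with Hmgcs1 at -1.33 ± 0.06. Of 35 interferon-stimulated genes 31 rose and 4 did not pass (median 0.58, adjusted p = 2.49e-08, and adjusted p = 0.0612 with an estimated correlation), led by Isg15 (1.64 ± 0.12). Of 22 p53 targets 17 rose, 4 fell and 1 did not pass (median 0.59, adjusted p = 0.000559, and adjusted p = 0.0641 with an estimated correlation). In antigen presentation and checkpoint genes 11 of 18 rose, 1 fell and 6 did not pass (median 0.27, adjusted p = 0.00137, and adjusted p = 0.0654 with an estimated correlation). Cd274, the gene of the checkpoint ligand PD-L1, rose by 1.06 ± 0.08.

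Counts of list members are over all genes tested. Adjusted over the list alone, they were the same for the ATF4, unfolded protein response, mitosis, replication, respiratory, hypoxia, glycolysis, interferon and p53 lists in sgControl cells. They differed by 1 gene for the NF-kB (24 rose), lysosome (2 fell), cholesterol (20 fell), lactate handling (9 fell) and antigen presentation (12 rose) lists. Of 26 lists tested, 18 passed camera with its preset correlation for lactate in sgControl cells, and 7 of these also passed with an estimated correlation. These were, with camera's adjusted p from the estimated correlation, ATF4 targets (0.00524), mitosis (0.00524), unfolded protein response (0.0203), DNA replication (0.0233), lysosome (0.025), respiratory chain (0.0371) and NF-kB targets (0.048). The matching counts were 20 and 2 (unfolded protein response, 0.0276, and mitosis, 0.0121) for lactate in sgHcar1 cells. They were 12 and 2 (ATF4 targets, 0.0162, and mitosis, 0.0458) for the difference between the lactate effects. Between guides they were 17 and 0 in PBS and 16 and 0 in lactate.

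**Figure D1:**
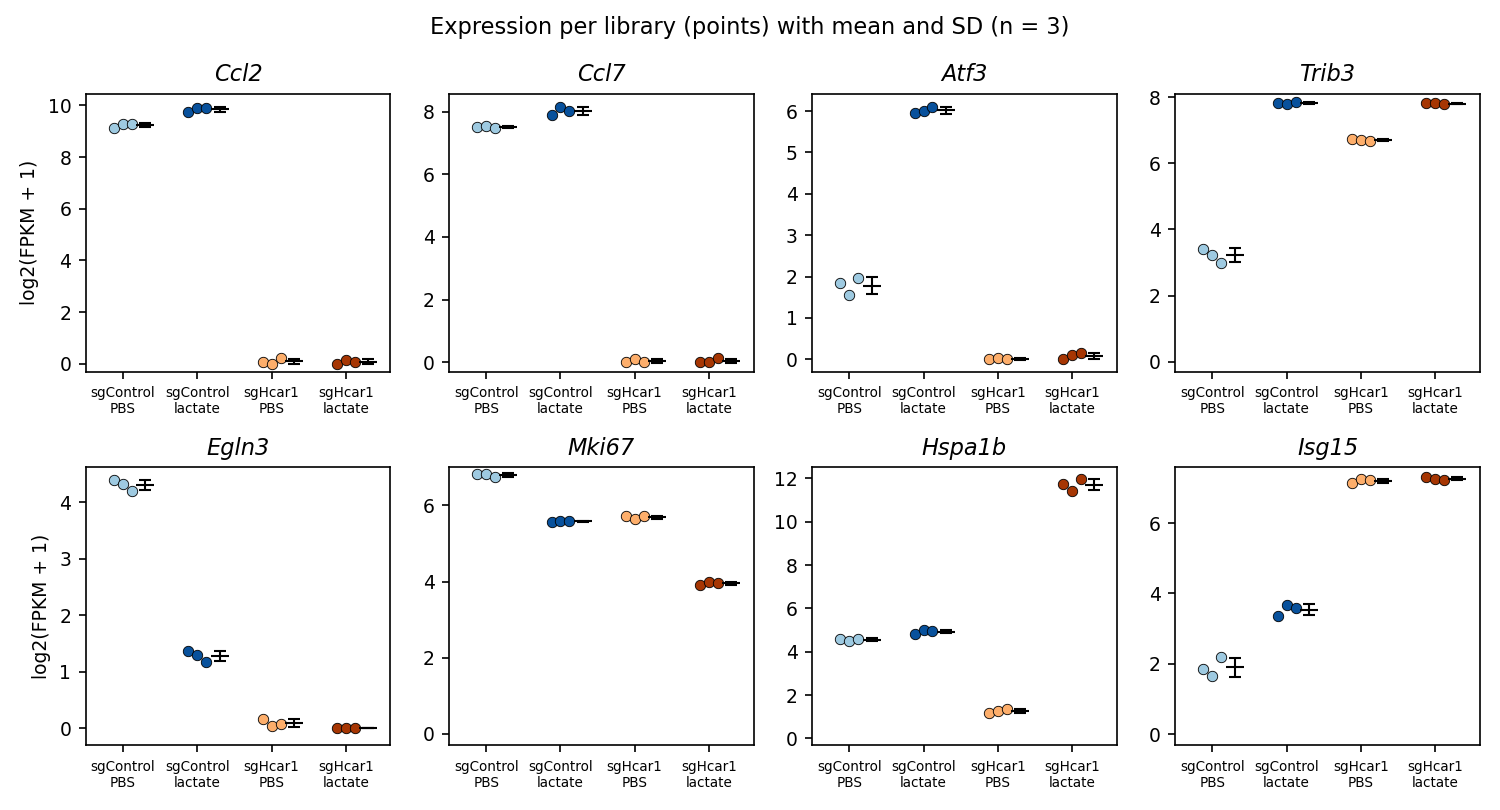
Level of 8 genes as log2 of FPKM + 1 (vertical axes) in the 4 groups (horizontal axes), with a point for each of the 12 libraries and the mean and SD of each group of 3 beside them. Ccl2 lies at 563 to 958 FPKM in sgControl libraries and at or under 0.159 in sgHcar1 libraries, and Hspa1b rises with lactate in sgHcar1 cells from 1.41 to 3386 FPKM in the group means.

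The next comparison asked what lactate did to sgHcar1 cells. The Hsp70 gene Hspa1b had the largest rise among the named genes and went from 1.41 ± 0.144 to 3386 ± 607 FPKM (log2 change 10.44 ± 0.11, n = 3 per group). Its partner Hsph1, a nucleotide exchange factor, went from 17.8 ± 0.707 to 1098 ± 117 FPKM (5.87 ± 0.06), and the co-chaperone Dnajb1 went from 32.2 ± 3.38 to 918 ± 120 FPKM (4.79 ± 0.09). Hmox1 rose from 24.4 ± 2.66 to 2393 ± 135 FPKM (6.57 ± 0.08). Txnip, a glucose-induced inhibitor of thioredoxin, fell from 79.1 ± 0.537 to 4.24 ± 0.324 FPKM (-3.94 ± 0.05), and the mitotic kinase Plk1 fell from 69.2 ± 3.86 to 7.03 ± 0.603 FPKM (-3.13 ± 0.07).

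In limma 9917 of the 13736 genes passed, 5050 higher and 4867 lower in lactate. Of these 2059 changed at least 2-fold (1213 higher, 846 lower). Other large rises were Ptgs2 (4.44 ± 0.05), the Hsp70 co-chaperone Bag3 (4.11 ± 0.09), the endoplasmic reticulum chaperone Dnajb9 (3.99 ± 0.05), the oxidative stress gene Osgin1 (3.78 ± 0.08) and Ppp1r15a (3.76 ± 0.04). Also among them was the microRNA locus Mir6395 (4.38 ± 0.26), where reads of a host transcript cannot be set apart. Other large falls were those of the MYC-network repressor Mxd3 (-3.56 ± 0.10), the CDK inhibitors Cdkn2c (-3.20 ± 0.07) and Cdkn2d (-2.89 ± 0.07), Ccna2 (-3.01 ± 0.04), Ankle1 (-2.99 ± 0.06) and the histone gene H2afx (-2.82 ± 0.06). Apln (-3.03 ± 0.06) and Acat3 (-2.83 ± 0.11) fell beside them. The largest adjusted p among the 10 rises was 4.52e-08 and among the 10 falls 1.72e-09. Hspa1a, the near-identical neighbour of Hspa1b, had no entry under that symbol, so reads of the pair were not set apart.

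Several lists moved in the same direction in sgHcar1 cells as in sgControl cells, though not all by the same amount. All 30 mitosis genes fell (median -1.75, camera adjusted p = 1.21e-16), with Cenpf at -2.52 ± 0.06 and Aurkb at -2.38 ± 0.04. All 23 unfolded protein response genes rose (median 1.69, adjusted p = 8.67e-13), with Dnajb9, Sdf2l1 (3.67 ± 0.08), Hspa5 (3.11 ± 0.02) and Creld2 (3.08 ± 0.07) in front. Of 30 DNA replication genes 27 fell, 1 rose and 2 did not pass (median -0.75, adjusted p = 5.64e-09, and adjusted p = 0.0522 with an estimated correlation). Of 37 ATF4 targets 28 rose, 4 fell and 5 did not pass (median 0.70, adjusted p = 2.95e-06, and adjusted p = 0.0562 with an estimated correlation), with Ddit3 at 2.54 ± 0.06 and Cebpb at 1.84 ± 0.06. Of 21 hypoxia-inducible genes 17 fell, 1 rose and 3 did not pass (median -1.04, adjusted p = 9.28e-06, and adjusted p = 0.123 with an estimated correlation). Of 14 glycolysis genes 12 fell and 2 did not pass (median -0.69, adjusted p = 1.14e-05, and adjusted p = 0.0675 with an estimated correlation). Of 24 cholesterol genes 22 fell and 1 rose (median -1.22, adjusted p = 1.41e-08, and adjusted p = 0.0675 with an estimated correlation). Of 16 fatty acid synthesis genes 12 fell and 3 rose (median -0.44, adjusted p = 0.000565, and adjusted p = 0.0522 with an estimated correlation), with Fasn, the fatty acid synthase, at -2.02 ± 0.06. In sgControl cells 9 of the 16 fell and 3 rose (median -0.20, adjusted p = 0.0302, and adjusted p = 0.14 with an estimated correlation).

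Stress and growth factor response lists also rose in sgHcar1 cells, and some of them in sgControl cells. Of 10 tested metallothionein and heat shock genes 8 rose and 2, the metallothionein genes Mt1 and Mt2, fell (median 1.72, camera adjusted p = 0.00253, and adjusted p = 0.156 with an estimated correlation). Of 22 NRF2 targets 17 rose, 3 fell and 2 did not pass (median 0.85, adjusted p = 6.25e-05, and adjusted p = 0.0675 with an estimated correlation), with Gclm, of glutathione synthesis, at 2.69 ± 0.06 and Srxn1 at 2.62 ± 0.04. Of 27 immediate early and MAPK feedback genes 20 rose, 4 fell and 3 did not pass (median 1.60, adjusted p = 2.38e-05, and adjusted p = 0.0675 with an estimated correlation), with the transcription factors Egr1 at 3.25 ± 0.06 and Fosb at 3.16 ± 0.11 and the EGF receptor ligand Areg at 3.18 ± 0.12. Of 28 NF-kB targets 21 rose, 2 fell and 5 did not pass (median 0.86, adjusted p = 1.17e-05, and adjusted p = 0.0675 with an estimated correlation), among them the neutrophil chemokine Cxcl1 (3.72 ± 0.06). In sgControl cells 14 of 22 NRF2 targets rose and 5 fell (median 0.28, adjusted p = 0.0165, and adjusted p = 0.213 with an estimated correlation). There 17 of 27 immediate early genes rose and 5 fell (median 0.32, adjusted p = 0.00562, and adjusted p = 0.183 with an estimated correlation). Ccl2 and Ccl7 stayed near 0 in sgHcar1 cells, at 0.0719 and 0.0271 FPKM in PBS and 0.0637 and 0.0314 FPKM in lactate. Of the 13 chemokines tested, 7 rose and 0 fell there (median 0.33, camera adjusted p = 0.0218, and adjusted p = 0.187 with an estimated correlation). In sgControl cells 7 rose and 2 fell (median 0.27, camera adjusted p = 0.0697). Counts adjusted over the list alone were the same for the lists given here, except that 13 glycolysis genes fell in sgHcar1 cells and 6 immediate early genes in sgControl cells.

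The difference between the lactate effects asked which responses to lactate were not alike in sgHcar1 and sgControl cells. The largest positive differences among the named genes were those of heat shock genes. Hspa1b changed by 0.36 ± 0.11 in sgControl cells against 10.44 ± 0.11 in sgHcar1 cells, a difference of 10.08 ± 0.15 (n = 3 per group). The differences were 6.10 ± 0.09 for Hsph1 and 5.12 ± 0.13 for Dnajb1. ATF4 targets went the other way. Trib3 reached 226 ± 4.19 FPKM in sgControl and 222 ± 2.25 FPKM in sgHcar1 cells with lactate, but from 8.39 ± 1.38 and 103 ± 1.95 FPKM, so its rise was smaller in sgHcar1 cells (-3.51 ± 0.11). Pck2, the mitochondrial PEP carboxykinase, rose in sgControl cells (2.09 ± 0.03) and fell in sgHcar1 cells (-0.37 ± 0.03), a difference of -2.46 ± 0.04.

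The difference passed limma's adjusted p of 0.05 for 8117 genes, 4170 with a higher and 3947 with a lower change in sgHcar1 cells. For 1068 it was at least 2-fold (575 and 493). The largest positive differences also held Arc, an activity-regulated gene (4.17 ± 0.23), Bag3 (3.64 ± 0.12), Cyr61, a matricellular protein gene (3.23 ± 0.10), and Dnajb4 (3.14 ± 0.09). They further held the microRNA loci Mir6395 (3.75 ± 0.37), Mir7048 (3.69 ± 0.64) and Mir6935 (3.19 ± 0.43). The largest negative ones held Atf3 (-4.18 ± 0.13), which was near 0 in sgHcar1 cells, the lipoprotein receptor Vldlr (-3.21 ± 0.06), Gdf15 (-2.94 ± 0.16), Akna, which was listed at 0 in all sgHcar1 libraries (-2.77 ± 0.07), and Chac1 (-2.66 ± 0.09). Next were Cth, of cysteine synthesis (-2.60 ± 0.18), the glycoprotein hormone Stc2 (-2.55 ± 0.10) and the folate enzyme Aldh1l2 (-2.45 ± 0.08). The largest adjusted p was 0.000512 among the 10 positive and 6.96e-07 among the 10 negative differences.

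Genes picked for a large change in sgControl cells are favoured by that choice to change less in sgHcar1 cells, and 59.1% of all genes passed the difference. The counts that follow therefore do not by themselves show a weaker response in sgHcar1 cells. Of the 10 genes with the largest rise in sgControl cells, 8 rose less in sgHcar1 cells, Hmox1 rose more (1.92 ± 0.12), and Ppp1r15a did not pass (0.09 ± 0.06). Under quantile normalization (-0.39, adjusted p = 8.55e-05) and with rescaling to one sum (-0.19, adjusted p = 0.0198) Ppp1r15a also rose less. The 8 were Trib3, Gdf15, Atf3, Chac1, Gadd45a (-1.20 ± 0.08), Car6 (-0.70 ± 0.08), Ddit3 (-1.38 ± 0.09) and Sh2d6 (-1.70 ± 0.09). Of the 10 with the largest fall, 6 fell less. These were Egln3 (2.94 ± 0.10) and Nrn1 (2.72 ± 0.08), which were both at or near 0 in sgHcar1 cells, Id3 (0.51 ± 0.15), Id2 (0.84 ± 0.18), Ankrd37 (0.73 ± 0.18) and Ldha (0.79 ± 0.06). The Id3 difference fell to 0.27 under the alternatives and its call ended at a pseudocount of 0.1 and with rescaling to one sum (adjusted p up to 0.215). Apln fell more on this scale (-0.34 ± 0.09), with the opposite sign at a pseudocount of 0.1 (1.91), and Bnip3 (0.47 ± 0.23), Klk10 (-0.20 ± 0.13) and Mir210 (0.12 ± 0.45) did not pass. The difference was -0.63 ± 0.10 for Ccl2 and -0.51 ± 0.09 for Ccl7, genes that were near 0 in sgHcar1 cells. Both calls ended at a pseudocount of 0.1, with adjusted p of 0.255 (range over the alternatives 9.52e-05 to 0.255) and 0.315 (0.000169 to 0.315).

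Among the lists, 33 of 37 ATF4 targets had a lower and 1 a higher change in sgHcar1 cells, with 3 not past the threshold (median -1.21, camera adjusted p = 3.14e-17). In mitosis 26 of 30 genes had a lower and 2 a higher one (median -0.55, adjusted p = 5.96e-09), among them Kif11 (-1.28 ± 0.05) and Ccna2 (-1.26 ± 0.05). Metallothionein and heat shock genes had a higher change in 7 of 10 and a lower one in 2 (median 1.99, adjusted p = 0.00151, and adjusted p = 0.211 with an estimated correlation). The unfolded protein response was higher in 17 of 23 and lower in 4 (median 0.46, adjusted p = 0.000336, and adjusted p = 0.211 with an estimated correlation), with Herpud1 (-1.57 ± 0.04) against the direction of Creld2 (1.42 ± 0.09). NRF2 targets were higher in 15 of 22 and lower in 1 (median 0.58, adjusted p = 0.000302, and adjusted p = 0.211 with an estimated correlation), with Nqo1 at 1.99 ± 0.10. Immediate early genes were higher in 15 of 27 and lower in 6 (median 0.52, adjusted p = 0.00572, and adjusted p = 0.238 with an estimated correlation), with Fosb at 3.05 ± 0.15 and Fos at 3.03 ± 0.13. Cholesterol genes were lower in 19 of 24 and higher in 2 (median -0.66, adjusted p = 9.06e-06, and adjusted p = 0.211 with an estimated correlation). Chemokines did not pass, with a higher change in 7 of 13 and a lower one in 4 (median 0.74, camera adjusted p = 0.192). Adjusted over the list alone the counts were the same, except that 3 NRF2 targets were lower and 8 chemokines higher.

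The lactate effects of the 2 populations were nevertheless related. Across genes, the log2 changes correlated with Pearson's r of 0.613 and Spearman's rho of 0.619, from different PBS libraries, and genes are not independent replicates. In both populations 3174 genes rose, where 1709.6 would be shared by independent lists (Fisher's exact odds ratio 8.26), and 2954 fell, where 1552.3 would be shared (8.05). Of 7149 genes called in both, 1021 changed in opposite directions. Every library was also rescaled to one FPKM sum, an alternative chosen after seeing the data. The filter was applied again to the rescaled values, so the genes tested and the weight of the added 1 differ from the main fit. The median change over the genes tested was then -0.105 for lactate in sgHcar1 cells, against 0 in the main fit. For the difference it was -0.175, against 0.0098. The gene splits became 4258 up against 6412 down and 2695 against 6002.

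**Figure D2:**
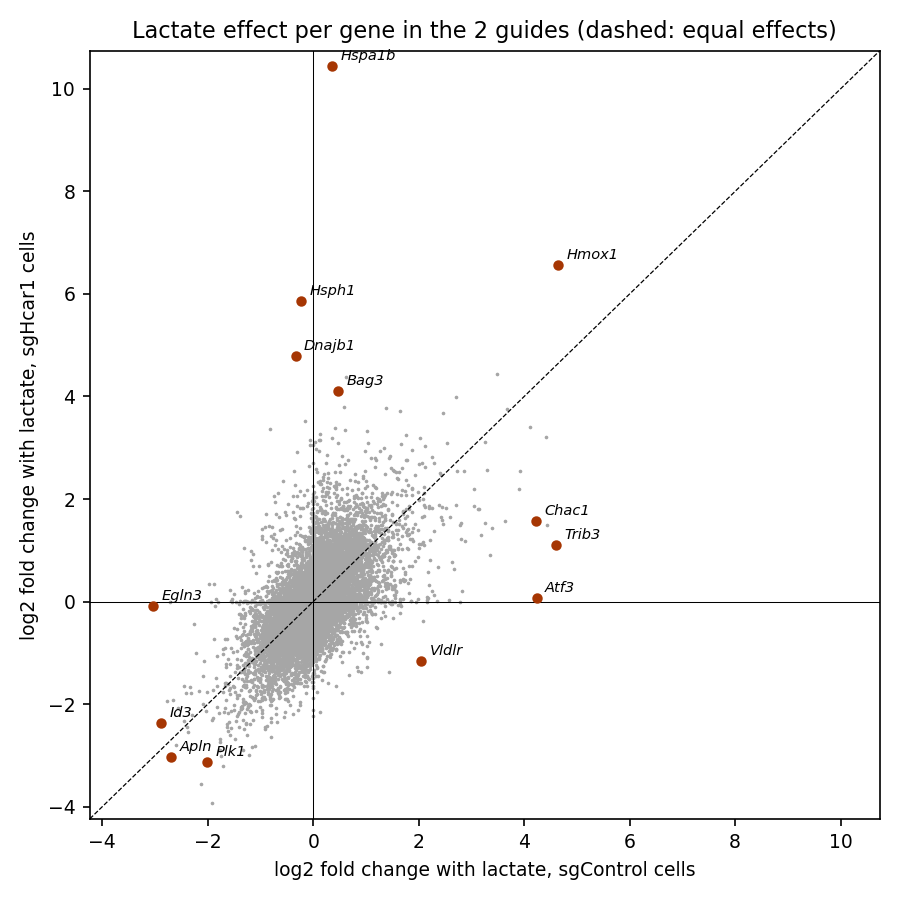
Log2 change with lactate in sgControl cells (horizontal axis) against that in sgHcar1 cells (vertical axis) for the 13736 genes tested, one point per gene, with some named genes labelled and a dashed line of equal change. Pearson's r is 0.613 across genes, and the heat shock genes Hspa1b, Hsph1 and Dnajb1 lie far above the line of equal change.

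The comparison of guides in PBS asked how sgHcar1 cells differed from sgControl cells without added lactate. The chemokine gene Ccl2 was at 597.5 ± 29.7 FPKM in sgControl cells and 0.0719 ± 0.0807 FPKM in sgHcar1 cells (log2 difference -9.13 ± 0.07, n = 3 per group). Ccl7 was at 181 ± 3.42 and 0.0271 ± 0.0469 FPKM (-7.47 ± 0.06). Mmp2, a gelatinase gene, was lower as well, at 301 ± 6.39 against 0.00714 ± 0.0124 FPKM (-8.23 ± 0.03). In the other direction, Esm1, an endocan proteoglycan gene, was at 0.0576 ± 0.0321 FPKM in sgControl and 241 ± 11.1 FPKM in sgHcar1 cells (7.84 ± 0.04). Rpl39l, a paralogue of a ribosomal protein gene, was listed at 0 in all sgControl libraries and at 229 ± 10.3 FPKM in sgHcar1 cells.

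Of 13736 genes, 10529 differed in limma, 5249 higher and 5280 lower in sgHcar1 cells. The difference was at least 2-fold for 2771 (1192 higher, 1579 lower). Higher in sgHcar1 cells were also the tight junction gene Cldn6 (7.37 ± 0.05), Baiap2l1 (7.01 ± 0.07), S100a7a (5.73 ± 0.05), Tmem176b (5.71 ± 0.09) and the keratin Krt18 (5.52 ± 0.04). So were the hypoxia-induced carbonic anhydrase Car9 (5.34 ± 0.08), the ubiquitin-like Isg15 (5.30 ± 0.12) and Ifi202b, which was listed at 0 in sgControl cells and at 59.8 ± 3.65 FPKM here. Lower were Crip1 (-7.68 ± 0.06), Ly6a, which encodes Sca-1 (-7.54 ± 0.13), the proteoglycan Bgn (-7.04 ± 0.06), Fstl1 (-7.00 ± 0.05) and the keratin Krt14 (-6.99 ± 0.05). So was Tgfbi, which stood at 168 ± 0.284 FPKM in sgControl cells and was listed at 0 in sgHcar1 cells. The largest adjusted p was 6.99e-12 among the 10 higher and 1.28e-12 among the 10 lower genes.

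Interferon-stimulated genes were higher in sgHcar1 cells in 34 of 35 cases and lower in 1 (median 1.97, camera adjusted p = 1.71e-12, and adjusted p = 0.0973 with an estimated correlation), with Oasl1 at 5.21 ± 0.06 and Rtp4 at 4.62 ± 0.06. ATF4 targets were higher in 30 of 37 and lower in 5 (median 1.06, adjusted p = 1.04e-07, and adjusted p = 0.0973 with an estimated correlation), with Sesn2, a leucine sensor, at 2.92 ± 0.08. Ribosomal protein genes were higher in 22 of 25 (median 0.61, adjusted p = 4.66e-06, and adjusted p = 0.249 with an estimated correlation). Hypoxia-inducible genes outside glycolysis were higher in 17 of 21 and lower in 4 (median 0.85, adjusted p = 0.00306, and adjusted p = 0.286 with an estimated correlation). Lower in sgHcar1 cells were 8 of 13 chemokines, with 4 higher (median -0.95, adjusted p = 0.029, and adjusted p = 0.249 with an estimated correlation). So were 19 of 24 cholesterol genes, with 1 higher (median -0.53, adjusted p = 0.000978, and adjusted p = 0.249 with an estimated correlation). Mesenchymal and matrix genes were lower in 20 of 34 and higher in 10 (median -0.49, adjusted p = 0.0494, and adjusted p = 0.249 with an estimated correlation). Col6a1 (-5.58 ± 0.03) and Col6a2 (-5.79 ± 0.04) were lower, while Col1a1, also a fibroblast marker, was higher (3.58 ± 0.07). Of 10 fibroblast markers 7 were lower and 2 higher (median -1.60, adjusted p = 0.0329, and adjusted p = 0.224 with an estimated correlation). Counts adjusted over the list alone were the same for these lists. The matrix call also ended under median-ratio scaling and without either sgControl PBS replicate 1 or sgHcar1 PBS replicate 3. After rescaling to one sum, over the genes that then passed the filter, the median was -0.156 against 0.0095 in the main fit, with 4411 genes higher and 7146 lower.

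The comparison of guides in lactate asked the same with lactate present. Ccl2 was at 921 ± 58.5 FPKM in sgControl and 0.0637 ± 0.0624 FPKM in sgHcar1 cells (log2 difference -9.76 ± 0.07, n = 3 per group). Ccl7 was at 260 ± 22.96 and 0.0314 ± 0.0544 FPKM (-7.98 ± 0.06). Hspa1b, lower in sgHcar1 cells in PBS (-3.30 ± 0.11), was higher in lactate (6.79 ± 0.11). Oasl1, an antiviral gene, was higher (6.41 ± 0.06), as was Csn3, which encodes a milk casein (5.69 ± 0.04).

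In limma 11292 genes differed, 5678 higher and 5614 lower in sgHcar1 cells. For 3759 the difference was at least 2-fold (1764 higher, 1995 lower). Rpl39l, Ifi202b, Cldn6 (7.09 ± 0.05), Baiap2l1 (6.99 ± 0.07), Esm1 (6.65 ± 0.04) and Tmem176b (5.94 ± 0.09) were again among the 10 highest, with Krt18, which was listed at 0 in sgControl cells in lactate and stood at 112.5 ± 2 FPKM in sgHcar1 cells. Mmp2 (-8.61 ± 0.03), Tgfbi (-7.68 ± 0.03), Bgn (-7.36 ± 0.06) and Fstl1 (-6.67 ± 0.05) were again among the 10 lowest, with the protease inhibitor Timp3 (-6.58 ± 0.04) and the fibrillin gene Fbn1 (-6.21 ± 0.04). Krt14, at 101 ± 6.68 FPKM in sgControl cells, and Slc7a2, a cationic amino acid carrier, at 84.9 ± 0.903 FPKM, were listed at 0 in sgHcar1 cells in lactate. The largest adjusted p was 4.02e-13 among the 10 higher and 2.04e-15 among the 10 lower genes.

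Among the lists in lactate, metallothionein and heat shock genes were higher in 7 of 10 and lower in 1 (median 2.77, camera adjusted p = 0.0035, and adjusted p = 0.21 with an estimated correlation). Interferon-stimulated genes were higher in 32 of 35 and lower in 1 (median 2.41, adjusted p = 1.04e-09, and adjusted p = 0.16 with an estimated correlation). Mitosis genes were lower in 24 of 30 and higher in 1 (median -0.51, adjusted p = 5.46e-05, and adjusted p = 0.16 with an estimated correlation), with Mki67 at -1.64 ± 0.03 and Top2a at -1.70 ± 0.03. Cholesterol genes were lower in 23 of 24 and higher in 1 (median -1.13, adjusted p = 3.95e-07, and adjusted p = 0.167 with an estimated correlation). Chemokines did not pass, with 8 of 13 lower and 5 higher (median -1.37, adjusted p = 0.238). ATF4 targets split, with 18 higher, 15 lower and 4 not past the threshold (median 0.05, mean -0.33, adjusted p = 0.88). Their median was below 0 under quantile normalization (-0.38) and after rescaling to one sum (-0.36). Counts adjusted over the list alone were the same for these lists. After rescaling to one sum, over the genes that then passed the filter, the median was -0.346 against 0.0054 in the main fit, with 4015 genes higher and 8540 lower.

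**Figure D3:**
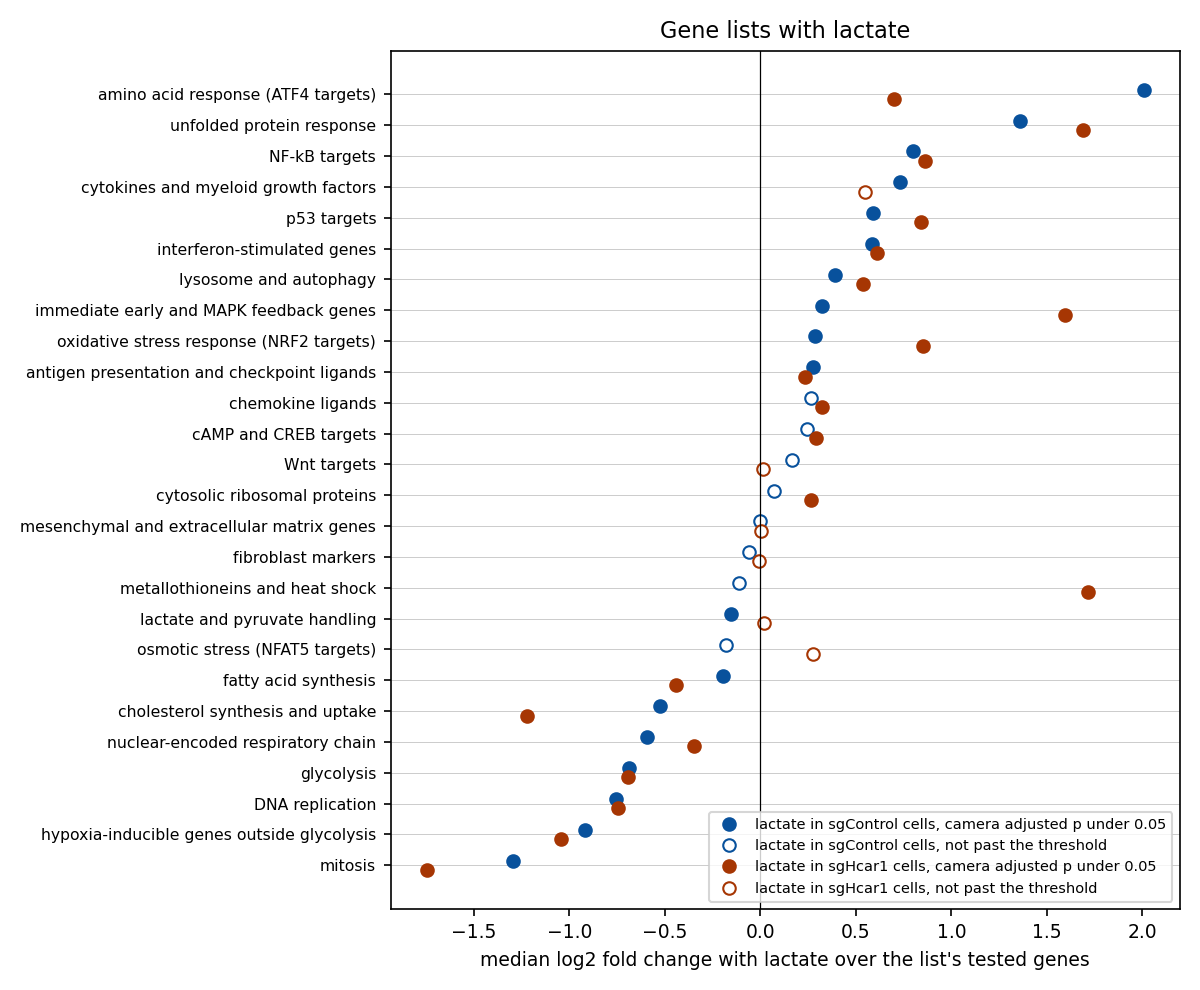
Median log2 change of the tested members of each gene list (vertical positions) in the lactate comparison of sgControl cells and that of sgHcar1 cells (horizontal axis), filled where camera's adjusted p with the preset correlation was under 0.05 and open otherwise. ATF4 targets have a median of 2.01 in sgControl cells and 0.70 in sgHcar1 cells, and the metallothionein and heat shock list has -0.11 and 1.72.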

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

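The difference between the lactate effects of sgHcar1 and sgControl cells was planned; the tests of explanations and the counts over other splits below were chosen only after these results were seen. What set the following results apart is that limma's test of the difference itself passed, or camera's for a list.

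The difference passed for 8117 of 13736 genes. The additive effects of guide and lactate were first taken out of the values, since they would swamp a regrouping. In all, 100 splits were drawn from the regroupings of treatment labels within each guide, the real one included. Of these 1 gave as many genes, the real one, and the highest of the others gave 1. A random assignment of these libraries to treatments would thus rarely give this count. Chance differences between cultures or populations are not excluded by it. The labels do not say whether the libraries of a group were separate cultures, and each guide is 1 population. For the pairwise contrasts, 3 against 3 libraries make 10 splits, too few for a share under 0.05: the real split gave 9031 genes for lactate in sgControl cells (highest other 1), 9917 for lactate in sgHcar1 cells (highest other 1), 10529 between guides in PBS (highest other 0) and 11292 between guides in lactate (highest other 1), and in each contrast 1 split gave as many.

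In the list of metallothionein and heat shock genes 7 of 10 had a higher and 2 a lower change with lactate in sgHcar1 than in sgControl cells, with a median difference of 1.99 (camera adjusted p = 0.00151, and adjusted p = 0.211 with an estimated correlation). The scaling of the libraries does not account for it, since the lowest median under the other scalings was 1.74 (quantile normalization, median-ratio scaling and rescaling to one sum). Nor does 1 aberrant library, since the lowest median without any 1 library was 1.92. A response of these cells to lactate may be the source, or the handling of the sgHcar1 lactate cultures; these cannot be told apart because all 3 libraries share the rise, and the median rise of the immediate early list (1.60, 20 of 27 higher and 4 lower, camera adjusted p = 0.0675 with an estimated correlation) would come with either. Of the 37 ATF4 targets, the list with the strongest opposite difference, 28 still rose in these cells.

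ATF4 targets gained less with lactate in sgHcar1 than in sgControl cells, with a median difference of -1.21. Scaling does not account for it, since the highest median under the other scalings was -1.20. A higher level before lactate is a candidate explanation, because 30 of the 37 genes already stood higher in sgHcar1 cells in PBS. In the form of a ceiling shared by both populations, it would by itself leave none of these genes lower in sgHcar1 cells in lactate. Of the 30, 9 ended lower than in sgControl cells in lactate, by a median of -0.52 (Atf4, Atf5, Chac1, Mthfd1l, Pck2, Slc1a4, Slc1a5, Slc6a9 and Slc7a5). However, 5614 of all 13736 genes tested were lower in sgHcar1 cells in lactate. Other differences between the populations could thus give this count, so it cannot exclude a shared ceiling. A ceiling that differs between the populations was not tested and stays open. For the others, 17 that ended higher and 4 that did not pass, a higher start and a weaker response cannot be told apart either. Both can leave them there. A role of Hcar1 was not tested.

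The other lists with a difference are given as medians. These were -0.66 for cholesterol synthesis and uptake, -0.39 for fatty acid synthesis, 0.46 for the unfolded protein response, 0.58 for NRF2 targets, -0.55 for mitosis, 0.36 for p53 targets, 0.52 for immediate early and MAPK feedback genes, -0.29 for mesenchymal and extracellular matrix genes, 0.24 for the nuclear-encoded respiratory chain and 0.23 for cytosolic ribosomal proteins, the last with the opposite sign under quantile normalization (-0.11). With an estimated correlation mitosis alone of these still passed (adjusted p = 0.0458). The others had an adjusted p of 0.177 (fatty acid synthesis), 0.238 (immediate early genes), 0.365 (ribosomal proteins) or 0.211 (the remaining lists).

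Of the 48 genes named for a lactate effect or for the difference, 44 passed, and so did Ccl2 (-0.63) and Ccl7 (-0.51). This count is no support for a difference, since genes named for the difference had to pass it. Of all genes tested, 59.1% passed. The change with lactate, not the level, was higher in sgHcar1 cells, as log2 differences, for Hspa1b 10.08, Hsph1 6.10, Dnajb1 5.12, Arc 4.17, Mir6395 3.75, Mir7048 3.69, Bag3 3.64, Cyr61 3.23, Mir6935 3.19, Dnajb4 3.14, Egln3 2.94, Nrn1 2.72, Osgin1 2.39, Hmox1 1.92, Dnajb9 1.29, Ptgs2 0.96, Id2 0.84, Ldha 0.79, Ankrd37 0.73 and Id3 0.51. This change was lower for Atf3 -4.18, Trib3 -3.51, Vldlr -3.21, Gdf15 -2.94, Akna -2.77, Chac1 -2.66, Cth -2.60, Stc2 -2.55, Pck2 -2.46, Aldh1l2 -2.45, Txnip -2.03, Ankle1 -1.76, H2afx -1.72, Sh2d6 -1.70, Acat3 -1.66, Cdkn2c -1.50, Mxd3 -1.43, Ddit3 -1.38, Ccna2 -1.26, Gadd45a -1.20, Plk1 -1.12, Cdkn2d -1.12, Car6 -0.70 and Apln -0.34. Egln3, Nrn1, Atf3, Akna, Cth, Ccl2 and Ccl7 were at or near 0 in sgHcar1 cells, so their differences carry little but the change in sgControl cells. Some calls did not hold under every alternative: those of Ccl2, Ccl7 and Id3 ended (adjusted p up to 0.255, 0.315 and 0.215), and Apln took the opposite sign at a pseudocount of 0.1 (1.91) and with rescaling to one sum (0.66).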

How the results depend on the processing

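Rescaling each library to one sum was chosen after seeing the data; the other alternatives were set before the data were examined. The counts of changed genes moved by over 1.5 times only with a stricter criterion, which by its construction calls fewer genes. A fold of at least 2 left 990 genes for lactate in sgControl cells, 2059 for lactate in sgHcar1 cells, 1068 for the difference, 2771 between guides in PBS and 3759 between guides in lactate. A mean of at least 5 FPKM, which tests fewer genes, left 6815 between guides in PBS and 7191 in lactate. Under every other alternative run, single left-out libraries included, the 5 counts stayed within 1.5 times.

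With the replicate number as a block the counts were 8938, 9899, 8044, 10480 and 11260, and no call of a named gene (122 results) or of a list (130) changed. The numbers do not pair the libraries: residuals of libraries that share a number correlated between -0.13 and 0.19 (mean 0.017, against -0.0086 for other numbers, over 8262 genes).

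Among named genes 2117 results kept direction and side of the threshold, 6 lost and 1 gained the call, and 14 reversed; the cause was not tested. The effects of lactate near 0 FPKM in sgHcar1 cells reversed without 1 library (Ccl2 -0.0588 to 0.0478, Ccl7 -0.0376 to 0.0433), and Ccl7 also under quantile normalization (-0.0038). The difference of the lactate effects reversed for Ppp1r15a under quantile normalization (-0.39) and rescaling (-0.19), for Apln at a pseudocount of 0.1 (1.91) and with rescaling (0.66), and for Mir210 without 1 library (-0.17 to 0.48). At a pseudocount of 0.1 the calls ended for Ccl2 and Ccl7 with lactate in sgControl cells and for the difference in Ccl2, Ccl7 and Id3. The Id3 call also ended with rescaling, and the Bnip3 difference passed without sgHcar1 PBS replicate 2 (0.63, from 0.47).

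For lists, 83 of 130 results passed, of which an estimated correlation ended 72 and left 11. Against the main calls fry added 33, quantile normalization ended 13 and added 4, rescaling ended 13 and added 4, median-ratio scaling ended 1, and leaving out 1 library ended 4 and added 1. Among list results that passed with or without an alternative, camera's direction reversed for ribosomal proteins in the difference (quantile normalization, -0.11), and fry's direction was opposite to camera's for hypoxia-inducible genes in the difference (median -0.12), for mitosis between guides in PBS (0.10), and for cytokines (0.35), ATF4 targets (0.0457) and cAMP targets (0.0779) between guides in lactate; the cause was not tested. The ATF4 median between guides in lactate, where camera did not pass, also changed sign under quantile normalization (-0.38) and rescaling (-0.36). Rescaling moved the median of all genes from 0 to -0.105 for lactate in sgHcar1 cells and from 0.0098 to -0.175 for the difference. Between guides the median moved from 0.0095 to -0.156 in PBS and from 0.0054 to -0.346 in lactate. The balance of rises and falls therefore depends on the scaling. The correlation of the lactate effects was 0.545 to 0.693 under all alternatives. A count test was not run, and unknown depth limits what can be said of genes near 0.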

Other observations

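The tests on genes near 0 in 1 guide and on chromosomes below were chosen only after the result was seen; the gene list tests were planned.

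Some planned lists have not been described above. Of 14 cytokine and growth factor genes 11 rose and 2 fell with lactate in sgControl cells (median 0.73, camera adjusted p = 0.0145, and adjusted p = 0.14 with an estimated correlation), with the secreted phosphoprotein Spp1 at 1.64 ± 0.04, Csf2 (GM-CSF) at 1.00 ± 0.15 and Csf1 at 0.98 ± 0.06, while Mif fell (-1.32 ± 0.04). In sgHcar1 cells 9 rose and 3 fell (adjusted p = 0.145), with Il23a at 2.18 ± 0.10. cAMP and CREB targets, genes downstream of the pathway that a Gi-coupled receptor lowers, rose in 9 of 16 and fell in 1 in sgControl cells (median 0.24, adjusted p = 0.0697) and rose in 10 and fell in 2 in sgHcar1 cells (median 0.29, adjusted p = 0.0393, and adjusted p = 0.301 with an estimated correlation), and the difference did not pass (median 0.13, adjusted p = 0.606). Osmotic stress genes did not pass for lactate in sgControl (median -0.18, adjusted p = 0.438) or sgHcar1 cells (median 0.28, adjusted p = 0.205). Between guides in PBS 9 of 10 were lower and 1 higher in sgHcar1 cells (median -1.35, adjusted p = 0.00185, and adjusted p = 0.249 with an estimated correlation), with the water channel Aqp1 at -2.67 ± 0.05. Wnt targets split, with 6 up and 3 down for lactate in sgControl cells (median 0.17, adjusted p = 0.593). Between guides in lactate 7 of 9 were lower and 2 higher in sgHcar1 cells (median -0.54, adjusted p = 0.0341, and adjusted p = 0.173 with an estimated correlation). Sox9, lower in sgHcar1 cells in PBS (-4.43 ± 0.09), rose there with lactate (2.34 ± 0.09). Counts adjusted over the list alone were the same for these lists.

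Most genes of the epithelial list had low values in both populations. Epcam and Cdx2, markers of intestinal epithelium, were listed at 0 in every library, Cdh1 was at 1.72 and 4.53 FPKM in sgControl cells in PBS and lactate and at 0 in sgHcar1 cells, and Krt18 showed the opposite pattern, with 46.2 and 112.5 FPKM in sgHcar1 cells. Of the mitochondrially encoded genes only mt-Nd6 had an entry, and it was listed at 0 throughout, so a listed 0 does not show that a gene was silent. Of the fibroblast markers, Thy1 and Lum were listed at 0 throughout.

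Many genes were present in 1 population and near 0 in the other. In all 6 sgControl libraries 138 genes reached 5 FPKM while all 6 sgHcar1 libraries stayed under 0.2 FPKM, and 37 genes did the reverse, 175 in all; for lactate the same rule found 1 gene in each direction in sgControl cells and 2 and 0 in sgHcar1 cells. Loss of chromosome segments that hold several expressed genes cannot be the cause for every one of the 138 genes near 0 in sgHcar1 cells. Of the 128 placed ones, 60.2% had both neighbours expressed there. That share was 81.1% for all genes, and 20 lay beside another such gene (mean of 1000 shuffles 3.13, highest 14). Loss of segments may account for some of the 138, but the shuffles cannot tell it from shared regulation of neighbouring genes. The 138 include related genes of the same chromosome, such as Ccl2, Ccl7 and Ccl8 on chromosome 11 and Hoxc9, Hoxc10 and Hoxc11 on chromosome 15. Loss of a single gene would leave its neighbours expressed, so the test of neighbours cannot exclude it. The 37 genes near 0 in sgControl cells were not tested in this way. The Hcar1 guide itself and a population that differs in other ways, as clones of a line can, cannot be told apart, since each guide is represented by 1 population and Hcar1 peaked at 0.0196 FPKM in any library. For that reason none of the differences between guides can be assigned to Hcar1 from these data.

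A difference in chromosome number between the populations is a hypothesis that could account for part of the broad differences. Among 7321 genes with a mean of at least 5 FPKM, the median difference between guides in PBS lay beyond every one of 1000 shuffles of the chromosome labels for 9 of 20 chromosomes, where the largest shuffled median was 0.19. Relative to all genes it was -0.59 on chromosome 8, where 15.2% of genes were higher in sgHcar1 cells, -0.46 on chromosome 14 and -0.41 on chromosome 11, against 0.35 on chromosome 6. In lactate 6 chromosomes lay beyond every shuffle, chromosome 8 again with the lowest median (-0.65), against 1 for lactate in sgControl cells (chromosome 18, 0.18) and 0 for lactate in sgHcar1 cells. Chromosome 16 had a median of -0.25 in PBS but -0.08 in lactate, where the largest shuffled median was 0.27. A difference in chromosome number could give medians that persist in lactate, but would not by itself account for this change on chromosome 16. DNA was not analysed here.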
